A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

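The deposited table holds 1 value per probe set for each of 2 Affymetrix Yeast Genome 2.0 arrays, 1 of untreated S. pombe cells and 1 of cells exposed to DETA NONOate. Per the labels' protocols, total RNA was isolated with a column kit and biotin-labelled cRNA was made from 250 ng of it. The authors' deposited values are probe set intensities on a linear scale, made with Affymetrix Expression Console per the submitters' processing notes. The version of that program and the algorithm that summarised probes into probe sets are not given in the sources used here. The values themselves showed a 2% trimmed mean of 500.29 and 500.32, so each array had been scaled to about 500, and the distributions of the arrays differed, so they had not been quantile normalized. A scaling of this kind makes ratios relative to the rest of the array, so that a common shift of all transcripts would not be seen. The groups were taken from the treatment given in the labels.

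Probe sets were named through a platform annotation, which can be old, and S. pombe names were updated by gene id through the RefSeq table of assembly ASM294v3, which gave 113 genes another name. That table served for names and for which genes neighbour each other, and no coordinates are printed because no genome build belongs to the array values. Of 10928 probe sets, 2914 named a single S. pombe gene (2896 genes, 14 of them with several probe sets), 2601 named an S. cerevisiae gene, 213 were controls, 20 named several genes, 3 could not be assigned to a species and 5177 had no name in the annotation. Probe sets with several genes, no settled species or no name entered no comparison. Named genes made up 56.4% of the 5124 protein-coding genes of the RefSeq table. Where a gene had several probe sets, the one with the highest mean signal was used. In the 7 such genes whose probe sets all reached a signal of 100, the log2 ratios of a gene's probe sets spanned a median of 0.07 and at most 0.23.

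The background level of each array, called the floor, was the 95th percentile of the S. cerevisiae probe sets, and lower values were raised to it before log2 was taken. Without the floor the S. cerevisiae probe sets had log2 ratios with an SD of 1.93, and 55.0% differed 2-fold or more. With it the SD was 0.11 and 5 of 2601 (0.19%) differed 2-fold, which follows from how the floor was set and tests nothing. A gene was measured if its signal passed the floor on at least 1 array, which held for 2889 genes, 2876 of them on both arrays. For the other 13 the ratio is a bound, written as at least so many fold. The ratio is the log2 signal on the treated array minus that on the untreated array. With 1 array per group no test of the treatment exists, so genes were counted at 2-fold or more and no p-value was computed.

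Before the data were examined, 29 gene lists were fixed from knowledge of S. pombe biology. For the 28 lists with at least 3 measured members, the median log2 ratio was ranked among the medians of 10000 random lists of the same size, drawn from measured genes in 20 bins of mean signal. A list was described as apart when its median lay outside the central 95% of random lists. Of the symbols in the lists, 6 had no match in the annotation. The rule for named genes, also fixed before the data were examined, took the 12 genes with the highest and the 12 with the lowest ratio, all members of the nitric oxide defence list, and in each other list up to 4 measured members with the largest absolute log2 ratio. It gave 111 genes. Another 29 genes, chosen after their values were seen, are named to complete or illustrate a list. They are sib1, abc3, str2, php4, bio2, isu1, isa2, nfs1, atp1, erg1, idi1 and erg11 in the results, and the genes named among the closing observations.

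The steps were tested on a simulated treated array, made from the untreated array plus noise. The noise had the spread of the brighter hybridization control probe sets. In the step that counts genes, run on 2883 genes, all 100 genes set 3-fold apart were counted at 2-fold, 0 of 100 genes set 1.5-fold apart were, and 0 of 2683 unchanged genes were. The changed genes were drawn from those with an untreated signal over 100. With noise this small against 2-fold, those counts follow from the settings and give no rate of false calls in the data. In the step that ranks lists, run on 2683 genes, 3.5% of 200 unchanged lists of 15 genes stood apart, and 100 lists raised 1.2-fold all did. That simulation holds hybridization noise, set the same for all genes. It leaves out labelling noise, the wider spread of dim genes and differences between cultures, so its rates do not carry over to the measured arrays.

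Alternatives fixed before the data were examined were thresholds of 1.5-fold and 3-fold, no floor with 16 added to each signal, a floor at the 99th percentile, median centring, quantile normalization, removal of a loess trend of ratio on signal (span 0.3), other rules for genes with several probe sets, random lists not matched on signal, and the mean in place of the median. The 8 gene lists of the closing observations, ranked in the same way, were chosen after seeing the data. Counts and lists restricted to genes that reached a signal of 100, and lists without members of an overlapping list, were likewise added later. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.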

Results

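RNA of log-phase fission yeast, Schizosaccharomyces pombe, was measured on 2 Affymetrix Yeast Genome 2.0 arrays. One array carried RNA of untreated cells, and the other carried RNA of cells exposed for 2 h to 0.5 mM DETA NONOate, a compound that releases nitric oxide slowly in solution. The comparison of the 2 arrays addresses how the transcriptome responds to this donor, in a series on nitric oxide signalling and oxidative stress. No array carries cells given the compound without nitric oxide release. Effects of nitric oxide and of the rest of the compound therefore cannot be told apart. The labels give no time for the untreated culture. Both cultures grew in the rich medium YES at 30 °C. The values are probe set signals on a linear scale, and their 2% trimmed mean was 500.29 on the untreated array and 500.32 on the treated array. The array also carries 2601 probe sets for Saccharomyces cerevisiae, which have no intended target in this RNA. Their 95th percentile, taken as the background level, was a signal of 7.99 on the untreated array and 8.76 on the treated array. The S. pombe probe sets had median signals of 759.7 and 751, and 2889 of the 2896 S. pombe genes with a named probe set of their own lay above background on at least 1 array.

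Each group has 1 array, so no difference reported here has a replicate check, no p-value is given, and the number of arrays limits the precision. The 63 probe sets for added control RNAs gave log2 ratios between the arrays with an SD of 0.24, and none of them differed 2-fold. That spread covers labelling and hybridization and leaves out differences between cultures. In the control transcript act1, the actin gene, the 3' and 5' parts had log2 ratios of 0.15 and 0.09. In the control transcript gpd3, a glyceraldehyde-3-phosphate dehydrogenase gene, these ratios were 0.28 and 1.62. Differences between the parts were mixed in the other controls, with 3' and 5' ratios of −0.23 and 0.46 for srb4, −1.78 and −2.16 for rip1, 0.27 and 0.03 for the TFIID control, and −0.26 and −0.49 for ura4.

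On the array of treated cells, the listed genes for iron uptake were much higher than on the array of untreated cells. Most of the listed iron-using genes and many respiratory genes were much lower. The iron lists were chosen as genes under the iron regulators Fep1 and Php4, with php4 itself. They therefore do not stand for all genes of iron-containing proteins. All 11 measured iron acquisition genes were at least 2-fold higher, with a median of 5.13-fold. Among 15 measured iron-using genes, a list of iron-sulphur cluster assembly genes, genes of iron-containing enzymes and electron carriers, and the vacuolar iron transporter gene pcl1, 12 were at least 2-fold lower. All 32 measured genes for the respiratory chain and the ATP synthase had a lower signal on the treated array, 17 of them by 2-fold or more. Targets of the oxidative stress regulator Pap1 and genes of the core environmental stress response had moderately higher medians, and genes for ribosome assembly had a lower one.

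Of the 2889 measured genes, 65 (2.25%) were at least 2-fold higher on the treated array, 59 (2.04%) were at least 2-fold lower, and 2765 (95.7%) lay within 2-fold. The median log2 ratio over all genes was −0.01, and the central 95% of genes lay between −0.90 and 0.95. A ratio of 4-fold or more was found for 13 genes in the higher direction and 11 in the lower. Among the 178 dim genes, with a signal under 100 on both arrays, 10.1% differed 2-fold or more, against 3.91% of the 2711 brighter genes. Of the 65 higher genes, 32 belonged to a gene list fixed before the data were examined, as did 31 of the 59 lower genes and 535 of all 2889 measured genes.

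**Figure D1:**
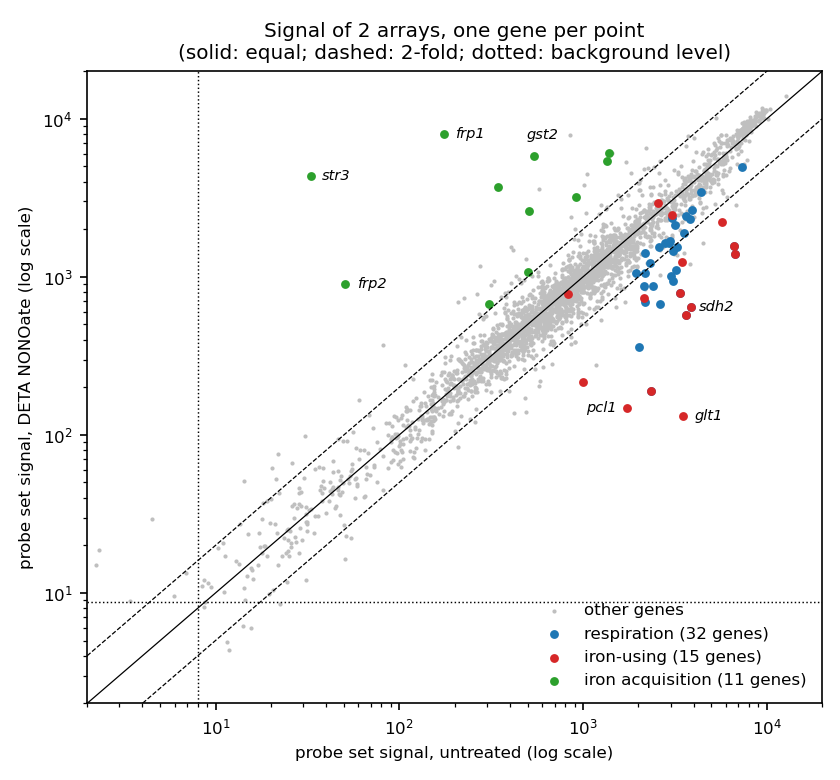
Signal of each measured gene on the untreated array (horizontal, log scale) and the DETA NONOate array (vertical, log scale), with 1 point per gene; the solid line marks equal signals, dashed lines 2-fold, and dotted lines the background levels of 7.99 and 8.76. The 11 iron acquisition genes (green) lie above the upper dashed line, while all 32 respiration genes (blue, or red where they are also among the iron-using genes) lie below the solid line.

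The gene with the highest ratio was str3 (SPAC1F8.03c), a siderophore-iron transporter gene, with a signal of 33.0 on the untreated and 4379 on the treated array, a 133-fold difference. The ferric reductase gene frp1 (SPBC1683.09c) had signals of 175 and 8039 and was 45.8-fold higher, and its relative frp2 (SPBC947.05c) was 17.6-fold higher. The iron permease gene fip1 (SPAC1F7.07c) and the ferroxidase gene fio1 (SPAC1F7.08), which neighbour each other in the genome, were both 10.7-fold higher. The remaining members were sib2 (5.13-fold) and sib1 (3.98-fold), which make the siderophore ferrichrome, the siderophore transporter genes str1 (4.37-fold) and str2 (2.19-fold), the vacuolar transporter gene abc3 (3.48-fold) and php4 (2.14-fold). Php4 is the subunit through which the CCAAT-binding complex represses iron-using genes when iron is scarce. The median log2 ratio of the 11 genes, 2.36, exceeded the medians of all 10000 random lists of the same size and similar signal.

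Iron-using genes showed the opposite direction. The glutamate synthase gene glt1 (SPAPB1E7.07), whose product is an iron-sulphur enzyme, had a signal of 3498 on the untreated and 132 on the treated array and was 26.4-fold lower, the lowest ratio of all measured genes. The gene called sdh4 on the array and tim18 in RefSeq (SPBP23A10.16) was 12.4-fold lower, and pcl1 (SPBC1683.10c), a vacuolar iron transporter gene, was 11.7-fold lower. In the genome pcl1 neighbours frp1, so that adjacent genes differed in opposite directions. Succinate dehydrogenase genes followed, with sdh3 6.33-fold, sdh2 6.05-fold and sdh1 4.20-fold lower. The iron-sulphur assembly gene isa1 was 4.64-fold lower, the biotin synthase gene bio2 2.90-fold lower, and the genes lys2 and leu2, for iron-sulphur enzymes of lysine and leucine synthesis, 2.77-fold and 2.56-fold lower. Of the 15 genes, 3 stayed within 2-fold, namely isu1, isa2 and nfs1 of iron-sulphur assembly, with log2 ratios of 0.20, −0.08 and −0.32. The list's median log2 ratio of −2.10 lay under the medians of all 10000 random lists.

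Respiration genes had a median log2 ratio of −1.05, again under all 10000 random lists, and the member with the ratio nearest to 0, atp1 of the ATP synthase, had −0.34. The haem-carrying complex III gene cyt1 was 5.55-fold lower, the cytochrome c gene cyc1 4.78-fold, the Rieske iron-sulphur protein gene rip1 4.28-fold and the complex III gene qcr9 3.90-fold. This list shares 6 measured genes with the iron-using list. Without them, 11 of 26 genes were at least 2-fold lower and the median was −0.89, still under all random lists. Respiration and iron-using genes together made up 23 of the 59 genes at least 2-fold lower.

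**Figure D2:**
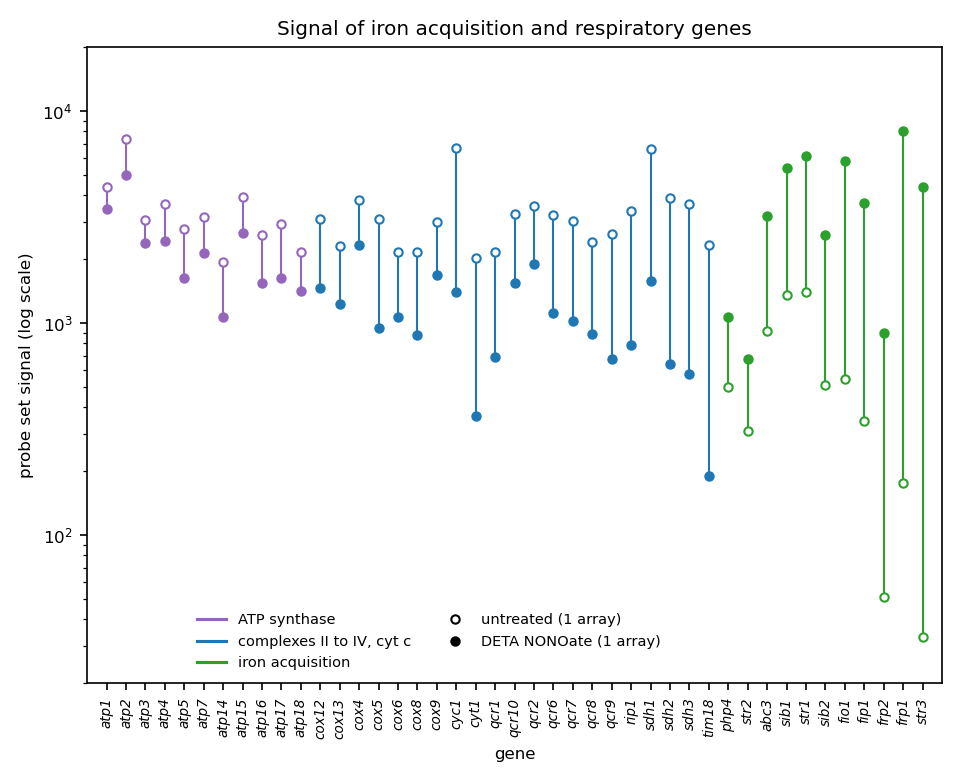
Signal (log scale) of each measured ATP synthase gene, each gene of respiratory complexes II to IV with cytochrome c, and each iron acquisition gene on the untreated array (open circle) and the DETA NONOate array (filled circle), 1 array each. Every respiratory and ATP synthase gene has its filled circle below the open one, from atp1 (log2 ratio −0.34) to tim18 (−3.63), and every iron acquisition gene has it above, up to str3 (7.05).

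Other metal genes differed less. Among 10 measured genes for copper and zinc, 3 were at least 2-fold higher and none 2-fold lower, with a median log2 ratio of 0.47 at percentile 99.96 of random lists. They were the metallothionein gene zym1 (3.74-fold) and the copper transporter genes ctr6 (2.25-fold) and ctr4 (2.02-fold), and ctr5, whose product works with that of ctr4, was 1.86-fold higher. Haem synthesis genes went both ways, and their median of 0.06 lay within random lists at percentile 71.0. Among the 7 measured, hem13, the coproporphyrinogen oxidase gene, was 2.15-fold higher, and hem3, the porphobilinogen deaminase gene, was 2.36-fold lower. The haem genes hem14 and hem1 were 1.60-fold and 1.42-fold higher.

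Genes for protection against oxidants were higher on balance. Among 11 measured Pap1 targets, 4 were at least 2-fold higher, 1 was 2-fold lower, and the median log2 ratio of 0.88 exceeded all random lists. The glutathione S-transferase gene gst2 (SPCC965.07c) had signals of 847 and 7865 and was 9.29-fold higher, and srx1 (SPBC106.02c), which encodes the peroxiredoxin-repairing enzyme sulfiredoxin, was 6.25-fold higher. The efflux transporter genes bfr1 and caf5 were 2.98-fold and 2.97-fold higher. The catalase gene ctt1 was the exception, with a signal of 2639 on the untreated and 1024 on the treated array, or 2.58-fold lower. In the wider antioxidant list of 22 measured genes, gst2 and srx1 were at least 2-fold higher, ctt1 and grx5 at least 2-fold lower, and 18 lay within 2-fold. The gene grx5, for a mitochondrial glutaredoxin of iron-sulphur assembly, was 4.23-fold lower. The median of the antioxidant list, 0.31, exceeded all random lists, and without the 7 genes it shares with the Pap1 list it was 0.24 at percentile 99.54. Of the 15 genes then left, 0 were at least 2-fold higher and 1, grx5, was at least 2-fold lower. No probe set carried a name from the list for nitric oxide removal, which held a flavohaemoglobin gene and the formaldehyde dehydrogenase genes fmd1 and fmd2, so these have no value here.

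The core environmental stress response, the gene set induced through the kinase Sty1 and the transcription factor Atf1, had 6 of 21 measured members at least 2-fold higher, ctt1 alone 2-fold lower, and 14 within 2-fold. The dehydrogenase gene tms1 was 3.79-fold higher, zym1 3.74-fold, and hri1, for a kinase of translation initiation factor, 2.81-fold. The median of 0.45 exceeded all random lists. Chaperone genes did not follow, since 0 of 18 differed 2-fold and the median of 0.12 lay at percentile 36.3 of random lists. Their largest ratios were −0.45 for mge1, 0.36 for hsp9, −0.31 for mcp60 and −0.28 for mas5. Efflux transporter genes had all 7 measured members higher on the treated array, with 2 of them, bfr1 and caf5, past 2-fold, pmd1 1.79-fold and hmt1 1.55-fold higher, and a median of 0.63 at percentile 99.99. The genes bfr1, caf5 and pmd1 are also Pap1 targets, and without these 3 the median of the other 4 genes was 0.37 at percentile 97.61, with none past 2-fold. Genes of autophagy and vacuolar proteolysis had 0 of 23 members past 2-fold, yet 21 of 23 had a ratio above 0, and the median of 0.49 exceeded all random lists. Their largest log2 ratios were 0.72 for atg6, 0.68 for atg5, and 0.66 for both atg17 and atg8.

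In the list of ergosterol synthesis and low-oxygen genes, 3 of 25 measured members were at least 2-fold higher and 22 lay within 2-fold. The gene for the transcription factor Sre1, the fission yeast counterpart of the mammalian sterol regulatory factor, was 4.26-fold higher, with signals of 1050.2 and 4477. The fumarate reductase gene osm1 was 2.75-fold higher, the sterol reductase gene erg24 2.05-fold, and dap1, which supports cytochrome enzymes of sterol synthesis, 1.95-fold. The list went both ways, since 9 of the 25 had ratios below 0, and the ergosterol synthesis genes erg1, idi1 and erg11 had log2 ratios of −0.82, −0.78 and −0.75. The median of 0.14 lay at percentile 98.5 of random lists matched on signal, and at percentile 97.2, within the range of random lists, when these were not matched. The F-box protein gene pof14 was 4.31-fold higher.

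Carbon metabolism differed by smaller amounts. In the glycolysis and fermentation list, 12 of 13 measured genes lay within 2-fold, and the alcohol dehydrogenase gene adh4 was 2.08-fold lower. The enolase gene eno102, the pyruvate kinase gene pyk1 and the phosphoglycerate kinase gene pgk1 had log2 ratios of 0.34, 0.34 and 0.31. The median of 0.27, against 0.16 for random lists of similarly bright genes, lay at percentile 99.97, whereas the mean of 0.13 lay at percentile 61.1. The median was 0.09 after quantile normalization and 0.12 with the loess trend removed, and pyk1 and pgk1 had log2 ratios of 0.16 and 0.14 after quantile normalization. Among 14 measured genes repressed by glucose, ght3, for a gluconate transporter of the hexose transporter family, was 4.58-fold higher, the invertase gene inv1 was 2.02-fold higher, and ght4 was 1.54-fold higher. The gene ght7 was over background on the untreated array only, at a signal of 22.4, and was at least 2.56-fold lower. Its log2 ratio was −0.65 with no floor and 16 added to each signal. That list had a median of 0.31 at percentile 99.93.

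The lists for ribosome assembly and amino acid synthesis had lower medians, while the ribosomal protein list lay within the range of random lists. All 30 measured ribosome assembly genes had ratios below 0, with a median of −0.46 under all random lists, although sda1, at 2.24-fold lower, was the single one past 2-fold. Next were mak16 with a log2 ratio of −0.94, rrp16 with −0.88 and rrp8 with −0.87. Genes of ribosomal proteins, many of which have near-identical copies that a probe set may not separate, had 0 of 111 members past 2-fold and a median of 0.16, at percentile 3.59 of random lists of similarly bright genes, which often are ribosomal protein genes themselves (107 of the 306 brightest); the median was −0.01 after quantile normalization. The outermost were rps1401 with −0.38, rpl3001 with 0.34, rpl8 with 0.33 and rps2202 with −0.31. Of 29 measured amino acid synthesis genes, 4 were at least 2-fold lower, 26 had ratios below 0, and the median of −0.31 lay under all random lists. Those 4 were glt1, lys2, leu2 and the histidine synthesis gene his5 (3.18-fold lower). Without the 3 genes shared with the iron-using list, the median was −0.30, still under all random lists.

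Genes transcribed at the start of S phase were higher, with 11 of 13 measured members above 0 and a median of 0.46, over all random lists. The gene cdt2, for the adaptor of a ubiquitin ligase active in S phase, was 3.27-fold higher and the single member past 2-fold. The ribonucleotide reductase gene cdc22 was 1.97-fold, the histone gene regulator ams2 1.96-fold and the replication initiation gene cdc18 1.58-fold higher. Histone genes, whose copies are nearly identical, had a median of 0.17 at percentile 96.2, with 0.27 for htb1, 0.25 for hht1 and 0.24 for hht3 and hhf3. Genes of mitosis and septation had a median of 0.02 at percentile 68.2, with −0.54 for slp1, 0.44 for eng1, −0.37 for chs2 and 0.30 for adg1. DNA repair and checkpoint genes had a median of 0.12 at percentile 95.8, and the checkpoint kinase gene cds1 had the largest log2 ratio, 0.49, followed by rhp14 with 0.46, rhp23 with −0.42 and mag1 with 0.39. No member of these 3 lists was 2-fold higher or lower.

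The remaining lists lay within the range of random lists. Among 11 genes induced by nitrogen limitation, the ammonium transporter gene amt1 was 3.52-fold lower, gln1, amt2 and isp6 had log2 ratios of −0.87, −0.55 and 0.55, and the median of 0.09 lay at percentile 83.4. In the list of sulphur assimilation and glutathione synthesis, cys2 and cys11 of cysteine synthesis were 2.04-fold and 2.02-fold higher, met14 and gcs1 had log2 ratios of −0.69 and 0.48, and the median over 12 genes was 0.14 at percentile 93.1. The 24 measured proteasome genes had a median of 0.11 at percentile 96.9, with 0.31 for pup3, 0.26 for rpn2, −0.23 for rpt5 and 0.21 for rpn8. Mating and meiosis genes (21 measured) had a median of 0.01 at percentile 70.7, with −0.94 for mei2, 0.83 for mfm3 and −0.66 for mfm2, and mei3 was over background on the treated array only, at least 1.68-fold higher. Phosphate and thiamine genes (8 measured) had a median of −0.10 at percentile 30.5, with 0.92 for the dim nmt1, −0.77 for vtc4, 0.70 for bsu1 and −0.53 for pho4. Cell wall genes (19 measured) had a median of −0.00 at percentile 53.2, with 0.63 for mok13, 0.54 for exg3, 0.44 for eng1 and −0.33 for gas5. Housekeeping genes (10 measured) had a median of 0.04 at percentile 46.7, with −0.31 for his3, 0.31 for fba1, 0.30 for tbp1 and −0.25 for cdc2. Apart from amt1, cys2 and cys11, no gene of these 7 lists was 2-fold higher or lower. The medians of the chaperone, mating and cell wall lists changed sign under at least 1 other scaling of the arrays.

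**Figure D3:**
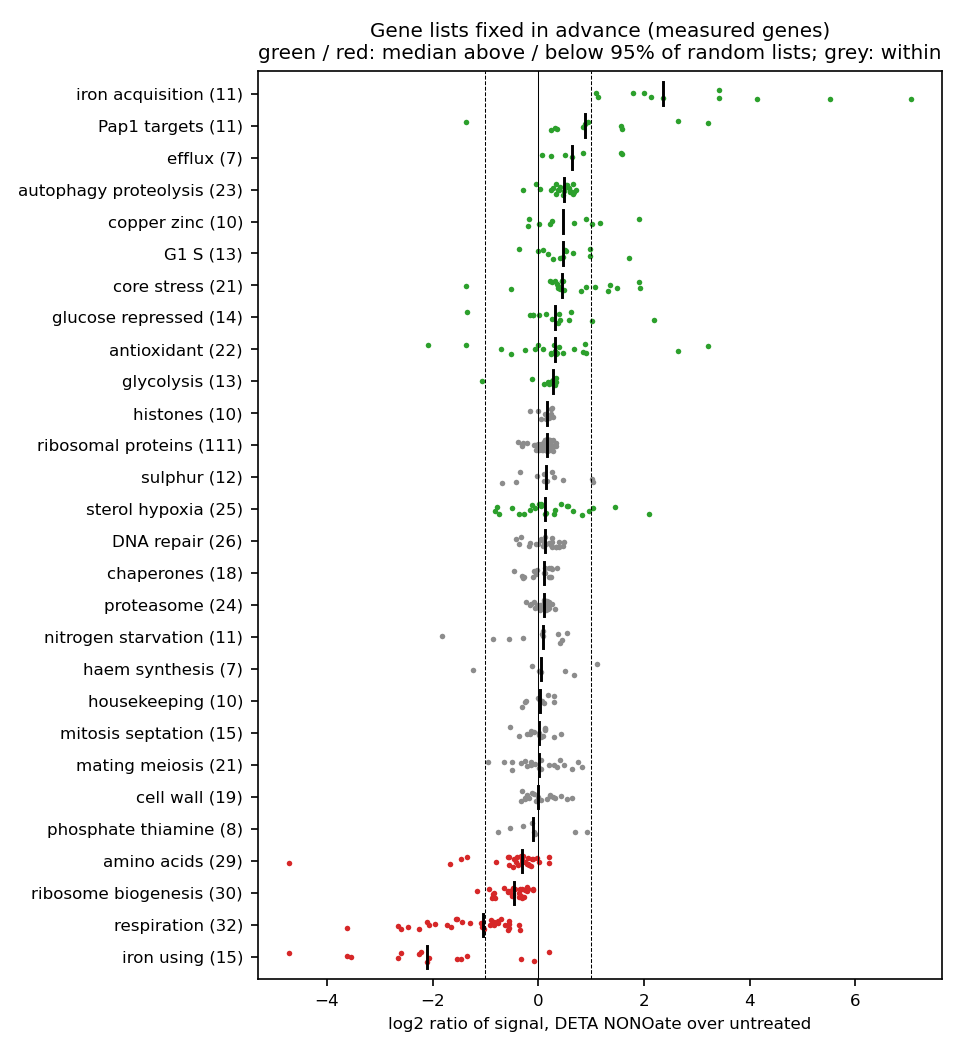
Log2 ratio of signal, DETA NONOate over untreated, for each measured gene (points) of the 28 ranked lists, with the list median as a vertical bar, measured genes in parentheses, and dashed lines at 2-fold. The 11 green lists have medians above the central 95% of random lists, from 0.14 for sterol and low-oxygen genes to 2.36 for iron acquisition, the 4 red lists have medians below it, and the grey lists lie between; the ribosomal protein median of 0.16 turns to −0.01 after quantile normalization, and the grey chaperone, mating and cell wall medians also change sign with the scaling.

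Of the 28 lists ranked, 15 had medians outside the central 95% of random lists, 11 higher and 4 lower. If the members of each list varied independently, as in random draws, 1.4 would be expected. Genes of a list are often regulated together and some lists share genes, so the 15 cannot be read as an excess over that number. These ranks describe the 2 arrays and carry no measure of how other cultures would differ.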

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

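Results were singled out here when a difference appeared in probe sets that the comparison of named genes does not use. No group holds enough arrays to look for an outlying sample.

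Among probe sets without a name in the annotation, 1881 were over background and reached a signal of 100 on at least 1 array. Of these, 77 were at least 2-fold higher and 52 at least 2-fold lower on the treated array. Among the 2711 named genes reaching 100, 53 were at least 2-fold higher and 53 at least 2-fold lower. None of the 63 probe sets for added control RNAs differed 2-fold, but these leave out differences between cultures. The annotation does not give the species that the unnamed probe sets were designed for. Of the named S. cerevisiae probe sets, 99% lay at or under signals of 13.2 on the untreated and 15.3 on the treated array, far under 100. The probe set 1774542_at had a signal of 10.1 on the untreated and 8271 on the treated array, 823-fold higher, more than for any named gene. The untreated signal lay close to the background of 7.99 and under the stricter floor of 13.2, and the ratio was at least 628-fold against that floor and 318-fold with 16 added to both signals. Probe set 1773014_at had a log2 ratio of 4.25, and 1779456_at and 1775304_at were 10.8-fold and 8.92-fold lower.

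Among the array's own control probe sets for S. pombe transcripts, all 3 parts of the rip1 control and 1 part of the gpd3 control differed by more than 2-fold. The 3' part of the rip1 control, for the Rieske iron-sulphur protein, had a log2 ratio of −1.78, and its middle and 5' parts had −2.22 and −2.16, close to the −2.10 of the gene's regular probe set. The 5' part of the gpd3 control, for a glyceraldehyde-3-phosphate dehydrogenase, had a log2 ratio of 1.62 with signals of 1941 and 5982, and its middle and 3' parts had 0.68 and 0.28.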

How the results depend on the processing

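The counts at 2-fold, 65 higher and 59 lower, ranged from 53 to 72 and from 53 to 59 over the other floors, scalings, probe set rules and the restriction to genes reaching a signal of 100, which was chosen after seeing the data. The size threshold moved them most, to 164 higher and 191 lower at 1.5-fold and to 26 higher and 18 lower at 3-fold, as a change of threshold must. Of the alternative values for list medians, 277 left the list on its side of the random lists, 6 moved it outside them, 2 moved it inside, and 0 reversed it. Median centring leaves every rank as it was, so its values among the 277 could not differ. Inside moved the sterol and low-oxygen list (0.14, percentile 97.2) with random lists not matched on signal, and glycolysis with the mean (0.13). Outside moved the proteasome (0.16) and histone (0.16) lists with the loess trend removed, DNA repair with quantile normalization (0.13) and with the loess trend removed (0.14), and ribosomal proteins, whose median of 0.16 lay above all random lists when these were not matched and at percentile 2.02, below matched lists, when only genes reaching 100 were kept. Their median was −0.01 after quantile normalization. The cause was not tested for these lists. Of 523 alternative values for the 66 named genes past 2-fold, 518 stayed past it in the same direction, and the other 5 belong to the dim genes ght7, wtf3 and wtf10. For ght7 they were −0.65 with no floor and 16 added to each signal, and −0.55 at the stricter floor. For a bright gene with 1 probe set, the probe set rules and the restriction to 100 return the same value. Many of the 518 values could therefore not differ. The genes ght7, mfm3, mei3, nmt1, wtf3, wtf10, wtf20 and wtf22 have no value when only genes reaching 100 are kept, and mei3 has none at the stricter floor. Signal over background limits dim genes, since 10.1% of genes under 100 on both arrays differed 2-fold. No paired analysis was possible because each group has 1 array, and no array could be left out for the same reason.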

Other observations

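The 8 gene lists added in this part were chosen after the data were seen, while the iron acquisition, iron-using, respiration and ribosomal protein lists were fixed before. The tests other than the test of scaling, and the genes named here, were also chosen after the data were seen. Beyond the respiratory chain, the other mitochondrial gene lists ranked here had lower medians on the treated array, with most members within 2-fold. Of 47 measured genes for mitochondrial ribosomal proteins, 43 had ratios below 0, with a median log2 ratio of −0.27 under all 10000 random lists, and mrpl16 (−1.24) was the single one past 2-fold. In the tricarboxylic acid cycle, with pyruvate dehydrogenase, 3 of 10 genes were at least 2-fold lower, namely the citrate synthase gene cit1 (−1.46), kgd2 of the ketoglutarate dehydrogenase complex (−1.38) and the lipoate synthase gene lip5 (−1.22), whose product is an iron-sulphur enzyme. The median was −0.46 at percentile 0.05, and the isocitrate dehydrogenase gene idh1 had 0.38. Mitochondrial protein import genes had a median of −0.28 at percentile 0.32, with 18 of 20 below 0, and tim50 had −1.49. Subunits of RNA polymerases I and III, the enzymes that make ribosomal and transfer RNA, were all below 0, 19 of 19, with a median of −0.48 under all random lists and −1.21 for rpc10.

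Genes for sphingolipid synthesis and breakdown had a median of 0.39 at percentile 99.94, with 3 of 11 past 2-fold. These were the hydroxylase gene sur2 with a log2 ratio of 1.65, imt2, for a mannosyl transferase of sphingolipid synthesis, with 1.47, and css1, for a phospholipase that breaks sphingolipids down, with 1.28. The hydroxylase gene scs7 was under 2-fold with 0.98. The wtf family, which includes meiotic driver genes, is repetitive, so that its probe sets may read several copies. It had 14 of 15 measured members above 0 and 5 past 2-fold. The family's median was 0.82, over all random lists, and 0.68 among members reaching a signal of 100. Of those 5, 4 had a signal under 100 on both arrays. They were wtf22 and wtf20, with log2 ratios of 1.83 and 1.62, wtf10, with 1.29, and wtf3, over background on the treated array only, with a bound of 1.22. With no floor and 16 added to each signal, the values were 1.14 for wtf22, 1.11 for wtf20, 0.87 for wtf10 and 0.92 for wtf3. At the stricter floor wtf3 had 0.50. Probe sets naming several wtf genes were left out of this list. The one for wtf13, wtf16 and wtf18 had a log2 ratio of −0.58, and the one for wtf5 and wtf10, near background, had 0.17. The others had 0.65, 0.79 and 0.81. The medians of these lists kept their sign under each scaling of the arrays. The gene fep1, for the repressor of iron acquisition genes, had signals of 423 and 137, a log2 ratio of −1.62.

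The higher iron acquisition genes and lower iron-using genes could come from the scaling of the arrays, from dim probe sets, from another difference between the cultures, or from the treatment. Over median centring, quantile normalization and loess removal, the iron acquisition median was at least 2.37 and the iron-using median at most −2.06. That test could hardly fail, since these steps move genes of similar signal by about the same amount, and the lists differed in opposite directions. The opposite directions themselves, with medians of 2.36 and −2.10 before these steps, argue against a scaling that moves all genes alike. All 23 members past 2-fold had a brighter signal of at least 10 times the floor. That rule could hardly fail, since 2711 of the 2889 measured genes reached 100 on at least 1 array. It also leaves out the dimmer array, where str3 had a signal of 33.0 and frp2 of 50.9. Dim probe sets are argued against for the list medians, because the genes at the medians were bright on both arrays. These were sib2, with signals of 507 and 2601, and rip1, with 3366 and 786. With no floor and 16 added to each signal the medians were 2.32 and −2.08. That setting could hardly move medians of such bright genes, so it tests little. Another difference between the cultures cannot be told apart from the treatment, because each group has 1 array. The treatment stays among the open explanations, as untested.

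A candidate explanation for the lower respiration genes is that only complexes carrying iron or haem are involved. On these 2 arrays lower ratios were not confined to such complexes. The ATP synthase carries neither, and its 11 subunit genes were all below 0, from −0.34 for atp1 to −0.87 for atp14. Their median log2 ratio was −0.57 at percentile 0.02. All 32 respiration genes, these 11 among them, were already known to lie below 0 when this comparison was set. It therefore describes the arrays and is no independent check. The 21 genes of complexes II to IV and cytochrome c had a median of −1.56, and 17 of them were past 2-fold, against 0 for the ATP synthase. The difference between the groups was not tested.

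The slightly positive median of ribosomal proteins, 0.16, may reflect a trend of ratio with signal between the arrays. Of the 306 genes in the brightest group, 107 are ribosomal protein genes, so a trend fitted on all genes is in part set by them and tests little. With the trend fitted on the other genes and removed, the median was 0.057, and the other 199 bright genes had a median of 0.05. These values leave the trend open as the whole account, and no biological explanation was tested.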
